A study of Mus musculus with 4 samples.

How the data were processed

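FLASH, a form of CLIP-seq, was done on WT26 cells, a feeder-independent male mouse embryonic stem (ES) cell line. In CLIP-seq, RNA is crosslinked to protein by ultraviolet light, the protein is pulled down with an antibody, and the RNA fragments that come with it are sequenced. There were 4 samples: 2 pulled down with a rabbit antibody against the RNA helicase DHX9 and 2 with rabbit IgG as the control, and each pair was labelled as biological replicates A and B. Per the labels' protocols, adapters carried random bases by which PCR duplicates were merged, a tag for the pulldown and a tag for the replicate, and control and DHX9 material was mixed before RNA was isolated.

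The authors deposited 1 list of peaks for the series. Per the file's source column the peaks were called with PEAKachu, a peak caller for CLIP-seq libraries; its version and settings are not given in the sources used here. Bowtie2 2.2.6 is named in the submitters' processing notes, which also name the genome builds hg19 and mm10; mm10 was taken for this mouse list, from its chromosome and scaffold names. Each peak in the deposited list has a first base, a last base and a strand. The score field was empty for all 59563 peaks, so the list gives no height, fold, p-value or read count, and nothing per replicate or for the IgG samples on their own. The contrast of DHX9 with IgG therefore enters only through the authors' calling, and the list does not state how the control was used. The sequencing depth behind a peak is unknown, and no between-replicate error can be given. Intervals and p-values below describe the placement of peaks over genes and positions in 1 list and not the spread between pulldowns. Peak numbers restart on each chromosome in the list.

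Genes were taken from a RefSeq table of assembly GRCm38.p6, the assembly that mm10 represents, with 49980 placed genes. The table gives a start, an end and a biotype for each gene, and neither strand nor exons. A peak was assigned to every gene whose body held its midpoint, on either strand, so a peak in overlapping genes was counted for each. Exons, introns, repeats and the B1 and B2 elements, which had been planned as comparisons before the data were examined, were not analysed here, because they need an exon annotation and the genome sequence. Because the table gives no strand, sense and antisense peaks were told apart only by which strand held most of a gene's peaks. Alternatives that needed a peak score or B1 positions were not run, and peaks of at least the median width took the place of the better-scoring peaks.

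The share of peaks inside gene bodies was compared with 1000 random placements of the same widths between the outermost gene or peak of each chromosome. For 14 gene lists fixed before the data were examined, the share of genes with at least 1 peak was compared with 10000 random lists of the same size, drawn from the same class (protein-coding or not) and length decile; p-values were two-sided permutation values with Benjamini-Hochberg adjustment over the 14 lists. Of the 280 list entries, in which 1 gene stands in 2 lists, 3 were not in the table. Position along genes was read along the strand of the peaks, in protein-coding genes of at least 20 kb with at least 5 peaks, at least 90% of which were on 1 strand, and tested by mirroring genes at random 10000 times. Small RNA genes inside host genes with at least 3 peaks were compared with 1000 random positions of the same length in the same host. For each chromosome, peaks in protein-coding genes were divided by the number expected from genes of the same length bin (of 50) on the other autosomes, with 95% intervals from a bootstrap over blocks of 5 Mb; length deciles gave a biased ratio in the simulated data and were replaced by these bins. X was also compared with draws of autosomal genes matched on length decile. On the mitochondrial genome, the bases covered on both strands were compared with 1000 circular shifts of 1 strand against the other. The position, small RNA, mitochondrial strand and single-autosome comparisons were chosen after the data were seen. Intervals on shares are 95% Wilson intervals and cover counting error only.

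The genes named were the 10 with the most peaks, the 10 protein-coding genes of at least 10 kb and 5 peaks with the most peaks per kb, up to 4 members of each list with the most peaks, and Dhx9. Peaks on either strand were counted for this rule, which had named the sense strand, and a part of it that ranked peaks by the authors' fold or p-value named no gene because the list holds neither. The values of 2 genes that the rule names are not reported here. Members of the lists outside this rule, genes from other families, snoRNA hosts and genes beside intergenic runs were chosen after their values were seen. The methods were tested on simulated data. In the simulated gene lists, 19 of 20 lists with 5 times the odds of a peak were called at an unadjusted p under 0.05, and 1 of 20 unchanged lists was. When each of the 19 autosomes was raised 1.5 times in turn, the mean of observed over expected was 1.47 and 18 intervals lay above 1; of the same 19 autosomes left unchanged, 17 intervals held 1. The alternatives tried were any overlap in place of the midpoint, protein-coding genes only, peaks within 50 bases merged, at least 3 peaks per gene, 1 peak per gene, peaks of at least the median width, other matching of genes, and leaving out chromosomes 8 and 11. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.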

Results

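DHX9 is an RNA helicase that unwinds RNA duplexes. The series asked which RNAs it binds in mouse ES cells, as part of a study of DHX9, RNA processing and transposable elements. The data consisted of the peaks called from 2 DHX9 pulldowns with 2 IgG pulldowns as controls. The list held 59563 peaks, 30481 on the plus strand and 29082 on the minus strand. Peaks had a median width of 196 bases, with quartiles of 146 and 268 bases, and together covered 12995 kb of the stranded genome. The median gap to the preceding peak on the same strand was 303 bases, so that peaks lay in runs. Merging peaks within 50 bases left 50655.

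Nearly all DHX9 peaks lay inside genes, and most of these were protein-coding. Of the 59563 peaks, 95.3% (95% interval 95.1 to 95.4%) had their midpoint in an annotated gene body and 92.7% (92.5 to 92.9%) in a protein-coding gene. Random placements gave a mean of 49.0% for all genes and 41.1% for protein-coding genes. The highest of the 1000 placements reached 49.7% and 41.9% (two-sided permutation p = 0.002 for both, the smallest that 1000 placements can give). Peaks called from RNA can lie only where RNA is made, so this excess does not speak of a preference of DHX9. Peaks in runs were placed independently, so the range of the placements is too narrow. Peaks were present in 4989 of 21900 protein-coding genes (22.8%) and in 550 of 12727 long noncoding RNA genes (4.32%). Pseudogenes rarely held a peak (113 of 9944), and none of the 394 V segments of the antigen receptor loci held a peak. These shares were not matched on length: the median was 910 bases for pseudogenes and 474 for V segments, against 17146 for protein-coding genes. In the shortest length decile of protein-coding genes, with a median of 0.942 kb, 2.47% held a peak. Within a gene, peaks lay almost entirely on 1 strand: in 1245 nuclear genes with at least 5 peaks and no overlapping gene, 86 of 23918 peaks (0.36%) were on the minority strand, and 97.1% of these genes had no such peak.

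Peaks were concentrated in a minority of the bound genes. A protein-coding gene with a peak held a median of 5, while 206 genes held at least 50 and 42 held at least 100; the 498 genes in the top 10% of the ranking held 48.2% of the peaks assigned to such genes. Longer genes held peaks more often, from 2.47% of genes in the shortest length decile to 37.9% in the ninth and 30.1% in the longest. Ankrd11, which encodes a chromatin regulator, held the most peaks, 222 over 159 kb (chromosome 8, 122883321 to 123042284), of which 177 lay in no other gene. It was followed by Enah, an actin regulator, with 211 peaks over 131 kb of chromosome 1 (181896384 to 182027556). Jarid2, a cofactor of Polycomb repressive complex 2, held 205 over 191 kb of chromosome 13 (44730774 to 44921643), of which 203 were on the plus strand. The corepressor gene Ctbp2 on chromosome 7 held 199 and the RNA-binding protein genes Rbpms on chromosome 8 and Msi2 on chromosome 11 held 186 and 180. Kat6b, a histone acetyltransferase gene, held 173, the cytoskeletal linker gene Macf1 held 171, and the actin nucleator gene Cobl and the nuclear transport gene Ranbp17 held 168 each. Except for 2 peaks in Jarid2, all peaks in these 10 genes were on 1 strand per gene.

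The most peaks per kb were in shorter genes, in an order that depended on how closely spaced peaks were counted. Ywhag, a 14-3-3 protein gene, had 65 peaks in 26.3 kb, or 2.47 peaks per kb (chromosome 5, 135908379 to 135934641), of which 49 lay in no other gene. Nop58, which encodes a core protein of box C/D snoRNPs and hosts snoRNAs, had 64 peaks or 2.41 per kb (chromosome 1, 59684961 to 59711510). The splicing factor gene Srsf3 followed with 25 peaks and 2.33 per kb, and the ES cell transcription factor gene Sall4 with 44 peaks and also 2.33 per kb. Bri3bp and Nufip2 had 45 and 75 peaks at 2.33 per kb each. The glycolytic enzyme gene Pkm had 52 peaks (2.28 per kb), the threonine dehydrogenase gene Tdh 38 (2.27 per kb, with 19 in no other gene), the 14-3-3 gene Ywhae 72 (2.18 per kb) and Vkorc1l1 97 (2.18 per kb). These densities counted closely spaced peaks apart. With peaks within 50 bases merged, Bri3bp came first at 1.81 per kb, Sall4 and Pkm had 1.70 and 1.67, and Ywhag, Nop58 and Srsf3 fell to 1.48, 1.32 and 1.21, so that 3 of these 10 genes stayed among the 10 highest.

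Genes that define ES cells held DHX9 peaks far more often than genes of the same length. Expression was not matched for this or any other gene list, so such an excess need not speak of a preference of DHX9. In the pluripotency list 21 of 28 genes (75%) had a peak, against a mean of 19.3% in matched random lists (3.88 times; permutation adjusted p = 0.0004 over the 14 lists). After Jarid2, the most peaks were in the DNA demethylase genes Tet1 (151, of which 123 in no other gene) and Tet2 (72) and in Trim71 (101), a developmental RNA-binding ubiquitin ligase gene. Among the core transcription factor genes Esrrb held 64, Nanog 13, Pou5f1 12 and Sox2 6, while Klf4, Dppa3 and Prdm14 held none. Markers of differentiated lineages had a peak in 1 of 16 genes, the tubulin gene Tubb3 with 7 peaks, and Afp, Cdx2 and Eomes had none; matched lists gave 18.5% (adjusted p = 0.39 by permutation). Of the 14 fibroblast markers, listed as a check for feeder cells, 2 had a peak: the fibronectin gene Fn1 with 63 and Loxl1 with 1. Col1a1 and Col1a2 had none (adjusted p = 0.40 by permutation). Long neuronal genes, listed because most are silent in ES cells, held 5 peaks in all, in 4 of 20 genes: Cntnap2 with 2 and Dab1, Lrp1b and Macrod2 with 1 each (matched lists 30.5%; adjusted p = 0.45 by permutation). With at least 3 peaks required per gene, none of the 20 remained and the adjusted permutation p was 0.029. Deciles match these genes poorly on length, since most are longer than the 185 kb median of the longest decile. With at least 1 peak, the ratio was 0.66 by decile and 0.88 when matched to the 100 genes of nearest length. The setting with at least 3 peaks was not run with nearest-length matching.

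Genes for splicing factors and RNA helicases held peaks more often than genes of the same length. Of 32 splicing factor genes 29 (90.6%) held peaks, against 24.8% in matched lists (3.65 times; permutation adjusted p = 0.0004), led by Celf1 with 109, Hnrnpc with 63, Hnrnpm with 34 and Tra2a with 32. The exceptions were Mbnl1, Mbnl2 and Ptbp2. Of 26 DExD/H-box helicase genes 19 held peaks (73.1% against 30.9%; permutation adjusted p = 0.0004). Dhx9 itself held 45, all on the minus strand (chromosome 1, 153455756 to 153487688), and Ddx46, Ddx17 and Ddx39b held 42, 36 and 19. Genes for proteins that bind or edit double-stranded RNA had peaks in 9 of 19 cases (47.4% against 30.6%; adjusted p = 0.23 by permutation), with Son at 31 and Dgcr8 and Zfr at 30 each, while Dicer1 and Eif2ak2 had none. For this list the threshold decided the call: with at least 3 peaks per gene the share was 2.34 times that of matched lists (permutation adjusted p = 0.020), and with peaks of at least the median width 2.08 times (permutation adjusted p = 0.039).

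The other protein-coding lists also lay above their matched lists. Genes for proteins linked to DHX9 in transcription and genome stability had peaks in 13 of 14 cases (permutation adjusted p = 0.0007): Top2a held 49, Polr2a, the largest subunit of RNA polymerase II, 40, Ctcf 38 and Xrcc5 31, and Wrn held none. DNA repair and replication genes had peaks in 16 of 24 cases (66.7% against 31.5%; permutation adjusted p = 0.0019), with Pola1 at 38, Brca2 at 25 and Mcm5 and Msh6 at 21. Genes known to give circular RNAs had peaks in 10 of 16 cases (62.5% against 28.5%; permutation adjusted p = 0.013), with Rtn4 at 78, Zfp609 at 27, Cdyl at 24 and Pan3 at 21, while Hipk3 and Foxo3 had none. The short ribosomal protein genes had peaks in 19 of 24 cases against 8.49% in matched lists (9.32 times; permutation adjusted p = 0.0004), with Rps24 at 14 and Rpl23 and Rpl4 at 9. Expression was not in the deposited list, and genes were matched on length alone.

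**Figure D1:**
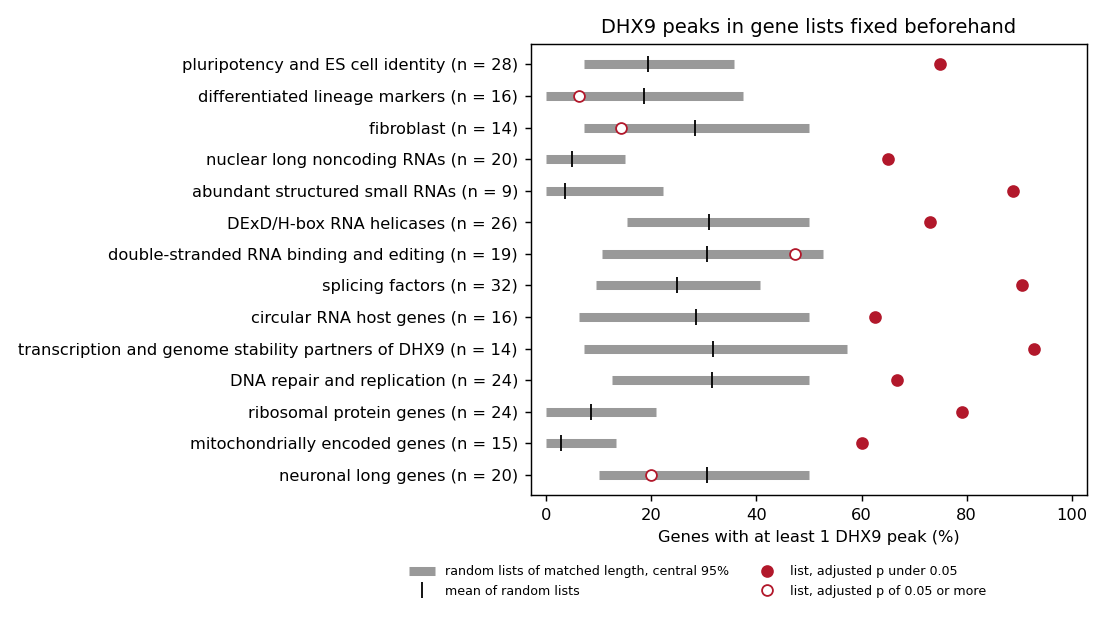
For each of the 14 gene lists, the point gives the percent of its genes with at least 1 DHX9 peak; grey bars give the central 95% of 10000 random lists matched on length and the tick their mean. Filled points mark the 10 lists with an adjusted permutation p under 0.05, all of them above their random lists.

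Noncoding RNAs listed as nuclear were also covered. Of 20 genes listed as nuclear long noncoding RNAs 13 had peaks, against 4.82% in matched lists (13.5 times, permutation adjusted p = 0.0004). The ratio was 30.7 with at least 3 peaks per gene. Some of these genes host snoRNAs that peaks overlapped: 8 of 8 in Snhg1, 4 of 5 in Gas5 and 4 of 4 in Snhg12. Their peaks are thus partly over snoRNAs. Pvt1 held 111 peaks over 222 kb of chromosome 15, all on the plus strand, Firre held 36 and Snhg14 held 39, of which 19 lay in no other gene. Tsix, the antisense transcript of the X-inactivation RNA Xist, held 53 peaks over 53.4 kb of chromosome X (103431517 to 103484957), all on the plus strand. Of these, 30 lay inside the Xist gene body and 23 outside it, and no peak in either gene lay on the minus strand. The 30 peaks counted for Xist are therefore on the strand that holds the peaks of Tsix alone, and with Xist counted as without a peak the list had 12 genes with peaks (12.6 times; permutation adjusted p = 0.0004). The abundant structured RNAs tested had a peak in 8 of 9 cases (permutation adjusted p = 0.0004), with 1 peak each over Rmrp, Rn7sk, Rnu11 and Rnu12, and also over Terc, the RNA of telomerase. Rn7s1, a signal recognition particle RNA gene, had none.

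**Figure D2:**
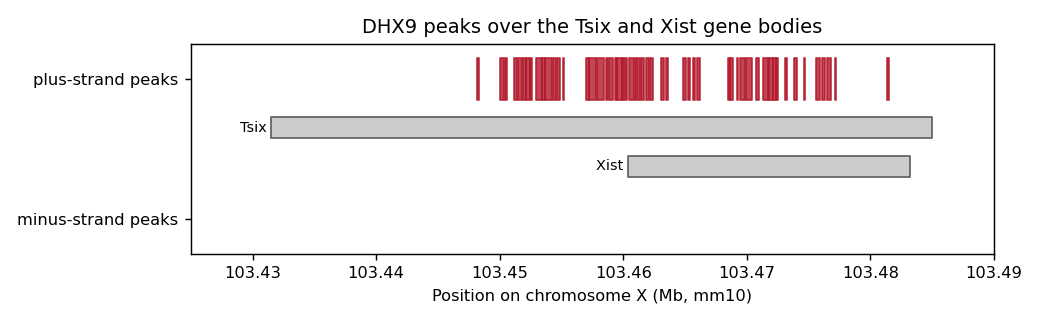
Peaks over the Tsix and Xist gene bodies by position on chromosome X in Mb (mm10); red bars are plus-strand peaks and no minus-strand peak was called. The 53 plus-strand peaks run across both sides of the Xist boundary, 30 of them inside Xist.

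Small RNA genes that lie inside bound host genes overlapped peaks more often than other positions in the same hosts did. Of 469 snoRNA genes in 159 hosts, 154 (32.8%, 95% interval 28.7 to 37.2%) overlapped a peak, against 19% for random positions (1.73 times; permutation adjusted p = 0.0027 over 4 classes). All 8 snoRNAs of Snhg1 and all 5 of Rpl4 overlapped peaks, as did 4 of 5 in Gas5 and 4 of 4 in Nop58. Among the 39 H/ACA box and 93 C/D box snoRNA genes so named, 20 and 48 held a peak midpoint. MicroRNA genes gave 64 of 291 against 12.4% (1.78 times; permutation adjusted p = 0.0027) and tRNA genes in hosts 13 of 18 against 10.8% (permutation adjusted p = 0.0027), while snRNA genes gave 12 of 106, close to the random 11.4% (permutation adjusted p = 1). With only peaks of at least the median width, the snoRNA ratio was 1.26 (permutation adjusted p = 0.080) and the tRNA ratio 1.23 (permutation adjusted p = 1), and with midpoints in place of overlap the microRNA ratio was 1.32 (permutation adjusted p = 0.48); each of these 3 calls was lost in that setting. With midpoints the snoRNA and tRNA ratios were higher, at 4.34 and 13.4 (permutation adjusted p = 0.0040 for both), and with the wider peaks the snRNA ratio was 0.38 (permutation adjusted p = 0.099).

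Along gene bodies, peaks were denser towards the end where transcription would begin if the peaks read in the direction of the gene. Over 1798 protein-coding genes, the first 20% of the gene body held a mean of 28.5% of a gene's peaks and the last 20% held 13.2%, a difference of 15.3 percentage points (95% bootstrap interval over genes 13.6 to 17.1; permutation p = 0.0001, the smallest that 10000 mirrorings can give). The first 20% held more in 1109 genes and the last 20% in 433. The difference was 11.1 points in genes of 20 to 50 kb, 18.3 points in genes of 50 to 100 kb and 21.2 points in genes of 100 kb and over (905, 519 and 374 genes). The gene table carries no strand, so direction was taken from the peaks. The peak list gives no amount of RNA along a gene, so uneven RNA and uneven binding cannot be told apart.

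**Figure D3:**
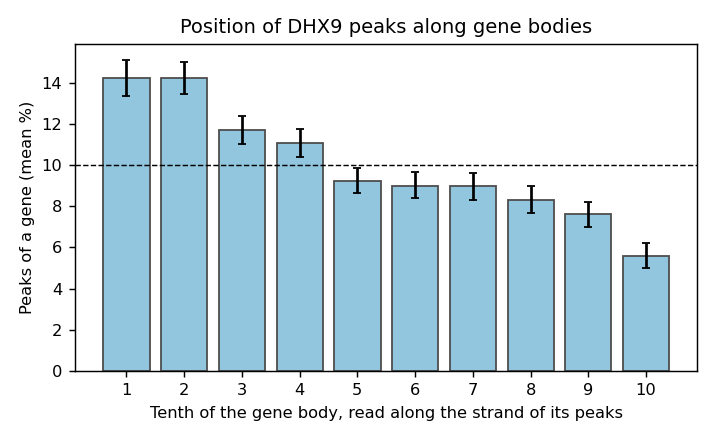
Mean percent of a gene's peaks in each successive 10% of its body, over 1798 protein-coding genes, read along the strand of the peaks; error bars are 95% bootstrap intervals over genes and the dashed line marks an even spread. The mean falls from 14.2% in the first bin to 5.60% in the last.

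Peaks were not spread evenly over chromosomes. Genes of chromosome X held fewer peaks than autosomal genes of the same length: 1086 in 966 genes, against 2331 expected (95% range of matched draws 1796 to 2943), a ratio of 0.47 (permutation p = 0.0002, the smallest that 10000 draws can give). The cells are male and carry a single X. The most peaks per gene were on chromosomes 11 and 8. Chromosome 11 held 7320 peaks, and its protein-coding genes held 1.96 times the number expected (95% interval 1.66 to 2.24). Chromosome 8 held 5170, and its genes 1.85 times the number expected (1.30 to 2.36). Per Mb of protein-coding gene length, there were 124 peaks on chromosome 11 (exact Poisson 95% interval 121 to 127), 95.2 on chromosome 8 (92.5 to 97.9), 33.2 to 66.3 on the other autosomes and 23.7 (22.3 to 25.1) on X; these intervals treat peaks as independent, which peaks in runs are not, and so are too narrow. In observed over expected peaks the other 17 autosomes ranged from 0.63 to 1.16 times, and none had an interval wholly above 1, while the intervals of chromosomes 3, 6, 7, 10, 12 and 14 lay wholly below 1. Peaks were found in 32.2% of the genes of chromosome 8 and 29.3% of those of chromosome 11, against 17.5 to 28.6% on the other autosomes and 12.5% on X. On each chromosome the expectation came from all other autosomes, so the values of the rest include the weight of chromosomes 8 and 11. Without these 2 chromosomes the X ratio was 0.53, and among genes that overlap no other gene it was 0.30 (permutation p = 0.0002 for both).

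**Figure D4:**
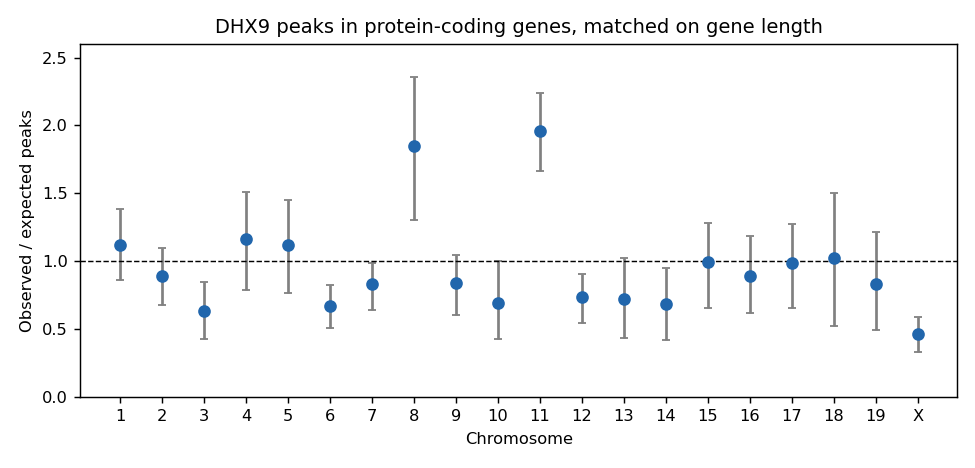
Observed over expected DHX9 peaks in protein-coding genes by chromosome, with the expectation from genes of like length on the other autosomes; error bars are 95% block bootstrap intervals and the dashed line marks 1. Chromosomes 8 and 11 stand at 1.85 and 1.96, and X at 0.46.

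The mitochondrial genome held 49 peaks, 16 on the plus strand and 33 on the minus strand. Over the whole mitochondrial genome the minority strand, here the plus strand, thus held 32.7% of peaks (95% interval 21.2 to 46.6%). Within single nuclear genes it held 0.36%. Which strand is the sense strand of each mitochondrial gene was not read, because gene strands were not available. Peaks lay over 9 of 15 mitochondrial rRNA and protein-coding genes, 22.1 times the share in genes of the same class and length decile (permutation adjusted p = 0.0004). The size of this ratio depended on the setting. It was 9.02 when matched to the 100 genes of nearest length, 37.0 with peaks of at least the median width and 98.5 with at least 3 peaks per gene. COX1 held 9, of which 3 on the plus and 6 on the minus strand, ND2 and CYTB held 5 each with 1 on the plus strand, and ND5 held 5 with 2 on the plus strand. Plus-strand peaks covered 6756 of 16299 bases, minus-strand peaks 8295, and 4749 bases were covered on both strands. No peak lay between bases 6579 and 10799, a stretch that holds the whole of COX2, ATP8, ATP6, COX3, ND3 and ND4L.

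**Figure D5:**
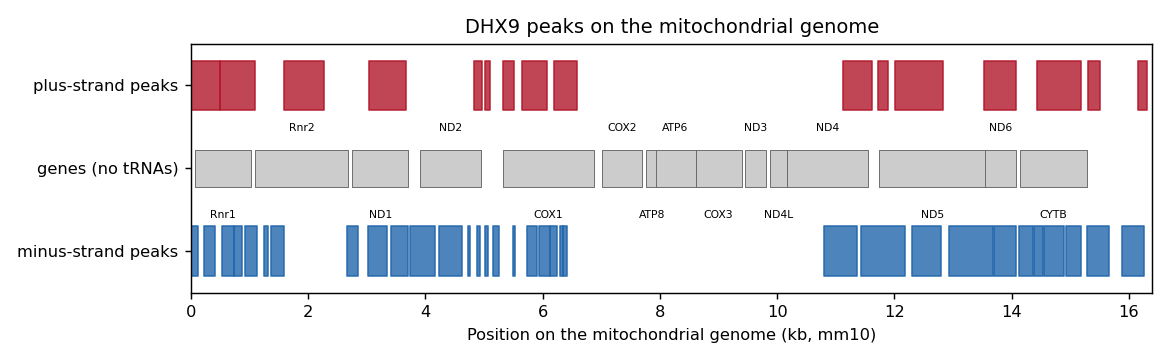
Peaks on the plus strand (red) and minus strand (blue) by position on the mitochondrial genome in kb (mm10), with rRNA and protein-coding genes in grey. Peaks on both strands lie on either side of a gap, where 4221 bases from 6579 to 10799 carry none.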

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

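The median-width filter, the exclusion of chromosomes 8 and 11, the nearest-length and gene-density matches, the restriction to genes that overlap no other gene, the count without Xist and every alternative of the position, small RNA and single-autosome results were chosen after seeing the data, as were any overlap for the gene lists and merging for counts and chromosomes. The main comparisons mostly kept their direction and their side of the threshold. Of 110 values recomputed for them, 1 count moved by over 1.5 times, 3 values no longer passed the threshold and 3 newly passed it. The rest kept both, except the snRNA ratio, never past the threshold, which went from 0.996 to 1.10 with midpoints. Both were kept in every setting run by the share of peaks in genes, the position along genes and the X ratio. The ratios of chromosomes 8 and 11 kept both too, with a lowest lower 95% bound of 1.07. The count of called gene lists, 10 as reported, also stayed within 1.5 times. Restricting to peaks of at least the median width left 29864 peaks; in that setting the ratio of snoRNA genes to random host positions was 1.26 and of tRNA genes 1.23, both no longer past the threshold, and the double-stranded RNA list rose to 2.08 times its matched lists and passed it. Requiring at least 3 peaks per gene took that list to 2.34 times and the long neuronal genes to 0 genes, a ratio of 0, both past the threshold. In that setting the abundant small RNAs gave no value, since neither the list nor its random lists held 3 peaks. Counting microRNA genes by peak midpoint gave 1.32, no longer past the threshold. The cause of these changes was not tested. Without chromosomes 8 and 11 the X ratio was 0.53. Among 70 named genes with peaks, assignment by any overlap moved no count by over 1.5 times and merging moved 13. The width filter moved 47. It removes all peaks narrower than the median, so these counts and the total of 29864 fell by its design. No paired analysis was possible because the deposited list holds no value per sample, and for the same reason no replicate could be left out and neither a count test nor a threshold on a peak score could be run; the alternatives on repeats and B1 copies, and matching on B1 copies, were not run either. With no read depth in the list, a gene without a peak cannot be told from a gene too weakly expressed to give one.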

Other observations

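The gene families in this paragraph and the runs of intergenic peaks were chosen after the data were seen, as were the mitochondrial tests on strand errors, duplexes and a nuclear copy. The excess on chromosomes 8 and 11 was also seen before its tests were chosen. The families were picked from the counts themselves, and several heterogeneous nuclear ribonucleoprotein genes are also in the splicing list, so their values are given without a p-value, beside the mean share in random protein-coding genes of the same length. Histone genes held a peak in 41 of 101 cases, against 2.48%. The linker histone genes H1f1 and H1f2 had 2 peaks each and the variant genes H2az2 and H3f3a 20 and 17. Peaks were present in 19 of 21 heterogeneous nuclear ribonucleoprotein genes (against 21.8%), 40 of 56 translation initiation factor genes (against 24.2%, with Eif3j1 at 43 peaks), 29 of 51 proteasome subunit genes (against 20.4%, with Psmd11 at 35) and 20 of 37 ubiquitin-conjugating enzyme genes (against 27.1%, with Ube2k at 90). Kdm histone demethylase genes had peaks in 12 of 18 cases (against 34.2%; Kdm5b held 84), Chd remodeller genes in 6 of 9 (against 32.8%) and Cbx genes in 5 of 8 (against 23.7%), where the Polycomb gene Cbx7 held 113 and the heterochromatin protein gene Cbx5 held 94. No peak was called in 1106 olfactory receptor genes (against 5.54%), 109 keratin and keratin-associated genes (against 8.86%) or 39 Hox genes (against 12.4%), and 1 of 92 cytochrome P450 genes had a peak (against 26.1%).

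Outside annotated genes, 2798 peaks lay on the assembled nuclear chromosomes, many in long runs on 1 strand. The run with the most peaks held 93 minus-strand peaks over 45.8 kb of chromosome 5 (33489545 to 33535348), between Nkx1-1 and Fam53a. The next held 92 plus-strand peaks over 46.7 kb of chromosome 1 (136567441 to 136614141), between Kif14 and Zfp281. A run of 69 minus-strand peaks on chromosome 16 (8757520 to 8792130) lay 0.45 kb from Usp7, which itself held 61 peaks. A run of 58 plus-strand peaks lay 0.26 kb from Rbmxl2 on chromosome 7, and a run of 51 minus-strand peaks 0.34 kb from Zfp202 on chromosome 9. Of 995 intergenic peaks within 10 kb of a gene with at least 3 peaks on the same strand, 688 (69.1%, 95% interval 66.2 to 71.9%) lay downstream of it along that strand and 307 upstream; peaks of 1 run are not independent, so no p-value is given. A further 9 peaks lay on 3 unplaced scaffolds.

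Genes of chromosomes 8 and 11 held 1.85 and 1.96 times the peaks expected from genes of like length. With each gene with a peak counted once, the ratios were 1.36 and 1.34, with lower 95% bounds of 1.10 and 1.21. Part of the excess thus came from more peaks per gene with a peak. Matching on gene density and length decile gave 1.78 and 1.63, with lower 95% bounds of 1.34 or more, and density with the 50 length bins, run because deciles alone were biased, gave 1.75 and 1.62 with bounds of 1.29 and 1.35, which argues against gene length and density as the whole cause. A single local stretch is also argued against, more clearly on chromosome 11. With each chromosome split into 3 equal segments, at least 2 segments of each had a lower bound above 1. The lower of the 2 second-lowest bounds was 1.17, on chromosome 8, while every bound on chromosome 11 was 1.32 or more. Segments were compared with autosomes other than chromosomes 8 and 11, in blocks of 2 Mb. That reference lowers the expectation, so segment ratios are not on the scale of 1.85 and 1.96, and the 1.17 may not hold there. Extra copies of these chromosomes, which are gains known to recur in cultured mouse ES cells, are a candidate explanation but remain open: the segments were uneven, at 1.23, 1.83 and 2.61 along chromosome 8 and 2.94, 2.03 and 1.73 along chromosome 11, and the lower bound of the first segment of chromosome 8 was 0.70. No biological explanation, such as higher expression of these genes, was tested, and the list holds no measure of copy number.

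The mitochondrial genome carried peaks on both strands, with 32.7% on the minority strand. This share was taken over the whole genome, whereas the nuclear shares below were taken within single genes. Within single mitochondrial genes, each of the 9 rRNA and protein-coding genes with a peak held peaks on both strands. Gene strands were not available, so sense and antisense peaks could not be told apart. The minority strand held 0.36% of peaks in nuclear genes and 1.01% in nuclear genes with at least 2 peaks per kb. Both values lie below the mitochondrial lower bound of 21.2%. They argue against strand errors of the library or the caller that give the same share of minority-strand peaks in all genes. Strand errors or crowding that rise with RNA abundance stay open. The list holds no read counts, and peaks per kb do not measure abundance. Binding to duplexes formed by transcripts of both strands may account for the pattern, but peaks of the 2 strands did not coincide beyond chance once the peak-free stretch was left out: 4749 bases were covered on both strands against a mean of 4635 in 1000 circular shifts (upper-tail permutation p = 0.28). With the stretch kept the p was 0.014, so that excess came from the stretch that neither strand covers. Binding of each strand's transcripts on their own stays open.

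The stretch of 4221 bases without peaks, from 6579 to 10799 of the mitochondrial genome, may reflect reads shared with a nuclear copy and lost or moved in mapping. The gene table lists Gm10925, a pseudogene of chromosome 1 (24613971 to 24614651) with mt-Atp6 among its synonyms and the same length of 681 bases as ATP6. Of the 6 coding genes inside the stretch 1, ATP6, has such a listed copy, and none of those outside has. A single peak lay within 5 kb of the copy, on the plus strand (24613084 to 24613144). Without the genome sequence the extent of the copy could not be measured, so shared reads and a true lack of binding cannot be told apart for these genes.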
